A study of Mus musculus with 16 samples.

How the data were processed

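Ly6G-positive neutrophils of C57BL/6 mice were sorted by flow cytometry (CD45, CD11b, Ly6G, DAPI) from blood, spleen and lung of GF and SPF animals, per the labels' protocols. RNA was amplified with a kit for low input that the protocols do not describe as marking strand, and was sequenced in paired-end mode. The submitters' processing notes name CASAVA for base calling, RSEM 1.3.1 for expected counts, limma and the mouse assembly mm10. The annotation version, the filter on low genes and the scaling between libraries are not stated. The protocols do not state how the organs were taken apart.

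The deposited file holds 1 linear signal value per gene and library, for 10296 genes and 16 libraries, with no unit in its header. In each library the smallest value is one step of 0.5 reads and nearly all low values are odd multiples of it, so the deposited signal has the form of an RSEM expected count plus 0.5, scaled by an effective library size (as in counts per 1e6 reads). One read is therefore worth 0.392 to 7.62 units, and a gene with 0 reads stands at 0.196 to 3.81, which is higher in shallow libraries. Reads were recovered by inverting this relation. Of values under 10 reads, 91.4% to 98.7% in a library lay within 0.05 of a whole read. The rest were fractional expected counts. Library depth, as reads recovered, ranged from 104213 to 3033941 (median 645992.5), and 1550 to 7262 genes had at least 10 reads. The 10 most abundant genes took 9.5% to 18.0% of the reads.

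Symbols and coordinates came from GENCODE M21 (GRCm38, the assembly mm10), where 10275 of the 10296 identifiers matched. Coordinates count from 1. There were 4 symbols that occurred on 2 lines. Genes with near-identical copies, among them haemoglobins, MHC class I genes such as H2-K1, Ly6c2, Chil3, ribosomal proteins and mitochondrial genes with nuclear copies, are uncertain because the counting could share their reads, and so are overlapping and antisense genes, because no strand-aware counting was stated.

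Genes with a value of at least 10 in at least 2 libraries were tested, which kept 8299 and removed 1997. A limit of 1 had been planned for scaled values, but the offset would have put nearly every gene above it, so the limit planned for counts was used. This was settled before any test. Differences were fitted in limma 3.58.1 on log2(value + 1), with the means of 6 groups in 1 model of all 16 libraries, a trended and robust prior, two-sided tests and Benjamini-Hochberg adjustment within each of 13 comparisons, with a threshold of 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values, while the offset of 0.5 reads, larger in shallow libraries, can raise or lower it. The comparisons were lung, spleen and blood against each other in GF and in SPF mice, GF minus SPF in each tissue and averaged over the 3 tissues, and the 3 interactions of tissue and status. Where all libraries of a group had 0 reads, the fold was bounded by the mean of the other group over a floor of 3 reads in the pooled libraries at 0. Floors cover counting error only. Lists were also given a median with such genes at their bound.

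Tested together were 24 gene lists in limma's camera with a preset correlation of 0.01, adjusted over the lists of a comparison: granule proteins, cell cycle, ageing and trafficking receptors, immediate early genes, NF-kB targets, interferon response, angiogenesis, hypoxia and glycolysis, oxidative phosphorylation, ribosomal proteins, pattern recognition, oxidase and phagocytosis, lysosome, MHC class II, B cells, T and NK cells, macrophages, dendritic cells, erythroid cells and platelets, eosinophils and mast cells, lung structural cells, mitochondrially encoded genes, circadian clock and glucocorticoid response. Of 312 list tests 100 passed. The number was 30 with the correlation estimated per list, and 71 with fry, which asks whether a list moves and not whether it moves more than other genes. The lists share members: 6 of the 29 macrophage, 5 of the 19 glucocorticoid and 5 of the 20 ageing receptor genes stand in another list.

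The comparisons, lists, alternatives and the rule for naming genes were written before the data were examined. By that rule the text draws from the 10 largest differences in each direction for tissue contrasts in GF mice and for GF minus SPF in a tissue, from 5 in the other comparisons, and from up to 4 members of smallest p per list. The genes had to pass, to reach a mean of 10 in the higher group and, in contrasts of 2 groups, to have no overlap between the groups. Chance gives such a gap in 10% of genes for 3 libraries against 3, in 20% for 2 against 3 and in 33.3% for 2 against 2. Predicted models, pseudogenes and receptor segments were not named, and part of the genes that the rule allows were left out for length.

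Alternatives were a pseudocount of 0.1 or 5, no filter, a limit of 100, quantile, median-ratio and TMM rescaling, no trended or robust prior, array weights, the compared groups alone, a replicate block, each library left out in turn, and edgeR 4.0.16 and DESeq2 1.42.0 on recovered reads of all 16 libraries, rounded where they were fractional. Voom weights, thinning of each library to 104211 reads and leaving out the 5 libraries under 250000 reads were added after the depths had been seen. Libraries of a group were checked for duplicates: the spread between them over that of counting alone, as chi-square per degree of freedom, ran from 1.98 to 13.7, so none was a copy. A library left alone in its group was assumed to vary like the others.

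The procedure was tested on simulated counts with the depths of these libraries and 200 changed genes. In GF lung against blood, with 7828 genes run, 46.5% of 4-fold changes were found, and 68.5% of 8-fold changes with 7870. For GF minus SPF, 4-fold changes were found in 29% of cases in blood, 56.5% in spleen and 54.5% in lung, while 2-fold changes were found in 1%, 9% and 3.5%, and in 46.5% when averaged over tissues. False calls for GF minus SPF in spleen numbered 21 beside the 113 true calls at 4-fold and 33 beside 156 at 8-fold. In GF lung against spleen there were 15 beside 126 at 4-fold and 10 beside 158 at 8-fold, in GF spleen against blood 6 beside 74 and 13 beside 134, and in GF lung against blood 7 beside 93 at 4-fold. In these simulations that is more than the threshold allows. With no gene changed, 0 to 2 of 7827 genes were called per comparison. Computation used R 4.3.3, Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.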

Results

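Neutrophils, the short-lived phagocytes marked by surface Ly6G, were sorted from the blood, spleen and lungs of C57BL/6 mice, and complementary DNA amplified from their RNA was sequenced. The mice were germ-free (GF, raised without microorganisms) or specific pathogen free (SPF, carrying a microbiota). The 16 libraries comprised 2 from GF blood, 2 from SPF blood, 3 from GF spleen, 3 from SPF spleen, 3 from GF lung and 3 from SPF lung, and 10296 genes were listed in each. Levels of genes are given as normalised counts, the deposited value less its offset of 0.5 reads, as mean ± SD over the libraries of a group, with n = 2 for blood and n = 3 for spleen and lung. The labels do not say whether the libraries of a group came from separate animals, so the p-values measure the spread between these libraries, which may be technical.

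Depth differed between the tissues. The median number of reads recovered per library was 2712907 in blood, 856319 in lung and 199487 in spleen, and single libraries ranged from 104213 (SPF spleen, replicate 1) to 3033941 (SPF blood, replicate 4). GF blood replicate 3, with 132798 reads, was far shallower than GF blood replicate 2, with 2555255. Between 3.1% and 37.7% of the genes had 0 reads in a library, and 1 read was worth 0.392 to 7.62 normalised counts, so a gene with few reads in a spleen library was measured coarsely. The median Spearman correlation between libraries of a group, across genes, ran from 0.828 in SPF spleen to 0.954 in SPF blood, against 0.788 between libraries of the same microbial status from different tissues. Between libraries of the same tissue and different status it was 0.881, above the medians within SPF spleen, GF spleen (0.857) and GF blood (0.876). The first principal component held 38.2% of the variance and the second 12%.

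**Figure D1:**
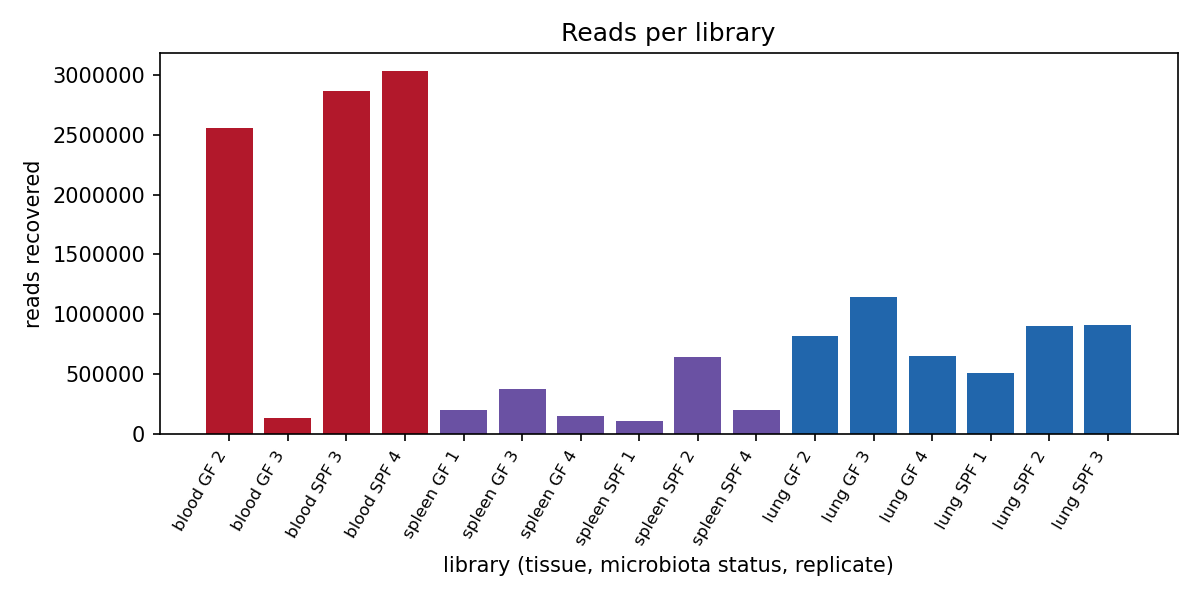
Bars give the number of sequencing reads recovered from each of the 16 libraries, grouped by tissue and microbial status. The 6 spleen libraries hold 104213 to 640596 reads and GF blood replicate 3 holds 132798, while the other 3 blood libraries hold 2555255 to 3033941.

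The series was described as an examination of how neutrophils of GF mice differ between tissues, and the first comparison set lung against blood. In GF mice, transcripts of inflammatory mediators were far more abundant in the libraries of lung neutrophils, which also held RNA of other cells. Cxcl2 (ENSMUSG00000058427, chromosome 5, 90903871 to 90905938, GRCm38), which encodes a neutrophil-attracting chemokine, measured 1117 ± 178 (SD, n = 3) in lung and 1.17 ± 1.65 (SD, n = 2) in blood (log2 difference 8.08, SE 0.51, adjusted p = 1.55e-12). Ptgs2 (ENSMUSG00000032487, chromosome 1, 150100031 to 150108227), the inducible cyclooxygenase, measured 2678 ± 329 against 4.87 ± 3.58 (8.66, adjusted p = 0.00012). Tnfaip3 and Nfkbiz, which encode an inhibitor and a coregulator in NF-kB signalling, differed by 5.63 and 5.31 on the log2 scale (adjusted p = 3.46e-12 and 5.9e-14). Of the 33 measured NF-kB targets and inflammatory cytokines, 21 were higher in lung (25 adjusted over the list alone) and 0 lower, with a median log2 difference of 2.49 (camera, adjusted p = 2.82e-23). Passing lists given with 1 adjusted p kept their call with an estimated correlation between genes, and the others are given with both values.

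Immediate early genes, which are transcribed within minutes of stimulation and also of tissue handling, were higher in GF lung than in GF blood in 15 of 28 cases (17 adjusted over the list alone). Of the rest 1 was lower (1 adjusted over the list alone), and the median difference was 1.82 (adjusted p = 1.04e-11). The transcription factors Egr1 and Nr4a1 measured 1017 ± 318 and 3092 ± 141 in lung against 3.94 ± 4.91 and 42.1 ± 7.21 in blood. Among angiogenesis and growth factors 6 of 11 rose (7 adjusted over the list alone, median 2.0, adjusted p = 4.65e-06, and adjusted p = 0.0505 with an estimated correlation). Nrp1, a co-receptor of vascular growth factors, was at 117 ± 25.0 in lung and at 0 reads in both blood libraries (at least 88.9-fold higher). The lung libraries also held transcripts of lung structural cells, given below. Whether these cells were the source of the angiogenesis transcripts was not tested. Trem1, which amplifies inflammatory signalling in myeloid cells, was higher in lung by 2.81 and Cd14, the co-receptor for bacterial lipopolysaccharide, by 3.36 (adjusted p = 7.6e-11 and 0.00179). The 32 pattern recognition genes did not pass as a list (adjusted p = 0.887), with 4 higher (5 adjusted over the list alone) and 2 lower (2 adjusted over the list alone). The chemokine receptor Cxcr2 was lower in lung (2708 ± 275 against 5586 ± 700.0; -1.04, adjusted p = 0.000213). Among the 20 ageing and trafficking receptors 3 were higher and 4 lower (3 and 4 adjusted over the list alone, adjusted p = 0.544).

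Transcripts of other cell types moved in the same comparison. Of 25 markers of lung epithelium, endothelium and stroma, 20 were higher in GF lung libraries (22 adjusted over the list alone) and 1 lower (1 adjusted over the list alone). Their median difference was 4.96, or 5.01 with genes at 0 reads in a group set at their bound (adjusted p = 9.07e-24). Sftpc (ENSMUSG00000022097, chromosome 14, 70520949 to 70524081), the surfactant protein of alveolar type II cells, measured 5533 ± 2179 in lung and 11.8 ± 4.19 in blood. The summed level of the list was 10950 ± 3880 against 612 ± 149. All 13 mitochondrially encoded genes were higher in lung (13 adjusted over the list alone, median 3.52, or 3.63 at the bound, adjusted p = 1.71e-23). Of 12 MHC class II genes 6 were higher (8 adjusted over the list alone, 1.94, adjusted p = 3.57e-05, and adjusted p = 0.0556 with an estimated correlation). B cell markers passed with 2 of 13 higher (6 adjusted over the list alone, median 1.57, adjusted p = 0.0378, and adjusted p = 0.385 with an estimated correlation). Dendritic cell markers did so with 2 of 4 (4 adjusted over the list alone, 2.04, adjusted p = 0.00659, and adjusted p = 0.0556 with an estimated correlation). Eosinophil, basophil and mast cell markers did so with 2 of 4 too (2 adjusted over the list alone, 2.24, adjusted p = 0.0366, and adjusted p = 0.107 with an estimated correlation). Of these 4 genes, Gata2 and Kit measured 69.0 ± 21.7 and 73.55 ± 28.6 in lung against 0.70 ± 0.99 each in blood. Hdc measured 3841 ± 152 against 4137 ± 748 and Ccr3 5.98 ± 2.05 against 3.74 ± 5.29. Erythroid and platelet markers were lower in lung, 11 of 15 (13 adjusted over the list alone, median -4.82, adjusted p = 1.87e-20). The platelet chemokine Ppbp was among them (6.41 ± 2.56 against 238 ± 11.6). Their summed level was 90900 ± 12500 in GF blood and 803 ± 1130 in GF lung.

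In all, 813 of the 8299 tested genes differed between GF lung and GF blood, 650 higher and 163 lower in lung (limma, Benjamini-Hochberg adjusted p under 0.05). The share of higher genes was 80.0%, and 65.8%, 64.0% and 65.7% after quantile, median-ratio and TMM rescaling, which shifted the median difference of all genes from 0.15 to -0.14, 0.00 and 0.02. Without lung GF replicate 4 the count was 524. Oxidative phosphorylation (1 of 50 higher, 0 adjusted over the list alone, adjusted p = 0.922) and ribosomal proteins (0 of 55 passing, 0 adjusted over the list alone, adjusted p = 0.728) did not pass as lists. Nor did lysosome and lipid handling, with 4 of 32 higher and 2 lower (5 and 2 adjusted over the list alone, adjusted p = 0.887), or T and NK cells (0 of 3 passing, adjusted p = 0.817).

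**Figure D2:**
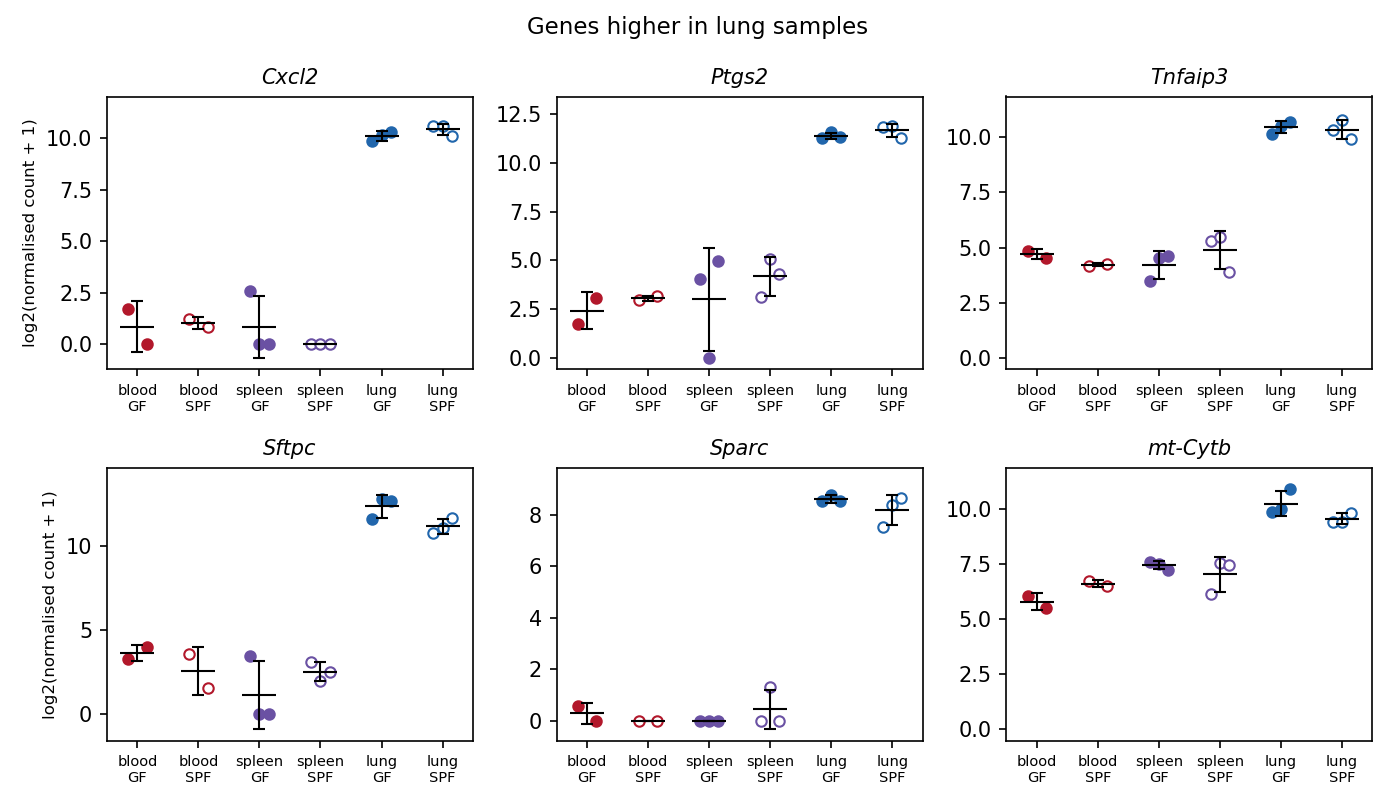
Each dot is the log2 of the normalised count plus 1 of a gene in 1 library (GF filled, SPF open) for the inflammatory genes Cxcl2, Ptgs2 and Tnfaip3, the lung cell markers Sftpc and Sparc and the mitochondrial gene mt-Cytb, and bars give the mean and SD of a group (n = 2 in blood, n = 3 elsewhere). Lung libraries of both statuses lie above the blood and spleen libraries for all 6 genes.

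Granule, macrophage and platelet transcripts were among those that differed between spleen and blood libraries of GF mice. Chil3, a secreted chitinase-like protein of neutrophil precursors and macrophages (ENSMUSG00000040809, chromosome 3, 106147554 to 106167564), measured 2507 ± 996 (SD, n = 3) in spleen and 97.5 ± 1.68 (SD, n = 2) in blood (4.57, SE 0.47, adjusted p = 7.73e-05). Cd177, a neutrophil surface protein, measured 1200 ± 376 against 352 ± 36.4 (1.72, adjusted p = 9.21e-05). Of 13 granule genes, 3 were higher in spleen (5 adjusted over the list alone) and 0 lower (median 0.89, adjusted p = 5.18e-10). Cybb, the catalytic subunit of the phagocyte oxidase, was 587 ± 225 against 120 ± 18.6 (2.21, adjusted p = 6.07e-05). It was 1 of 2 genes higher among the 19 oxidase and phagocytosis genes (2 adjusted over the list alone), a list that did not pass.

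Markers of resident splenic and other cells accompanied these differences. Among 16 macrophage and monocyte markers 3 were higher in GF spleen (8 adjusted over the list alone) and 0 lower (1 adjusted over the list alone, median 0.94, adjusted p = 1.54e-06). These were Chil3, the immediate early gene Nr4a1 (1.66, lost with any of 5 single libraries left out) and the adhesion molecule Vcam1 (4.49, lost at equal depth). Of its 29 genes before filtering, 6 also stand in other lists. MHC class II genes were higher in 3 of 12 cases (7 adjusted over the list alone, 1.51, adjusted p = 7.66e-07), led by H2-Ab1 (52.6 ± 6.77 against 6.04 ± 1.93). B cell markers passed with 1 of 13 higher (3 adjusted over the list alone, 0.60, adjusted p = 0.0206, and adjusted p = 0.49 with an estimated correlation). Mitochondrially encoded genes passed with 5 of 13 (7 adjusted over the list alone, 1.18, or 0.98 with genes at 0 reads at their bound, adjusted p = 1.7e-10, and adjusted p = 0.12 with an estimated correlation). Platelet genes were lower in spleen: Ppbp was 5.29 ± 4.98 against 238 ± 11.6. Itga2b, the platelet integrin subunit, was at 0 reads in the 3 spleen libraries and 159 ± 67.3 in blood, at least 40.7-fold lower. In the erythroid and platelet list 8 of 15 were lower (13 adjusted over the list alone, -4.50, adjusted p = 1.37e-28).

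Between GF spleen and GF blood 73 genes differed, 39 higher and 34 lower in spleen. The count rested on few libraries. It was 29 without blood GF replicate 3, 153 without blood GF replicate 2 and 153 without spleen SPF replicate 1. Without the 5 libraries under 250000 reads it was 114, and the call for Chil3 was then lost (4.43).

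Granule protein transcripts separated lung from spleen libraries. In GF mice Ltf (ENSMUSG00000032496, chromosome 9, 111019271 to 111042767), which encodes lactoferrin of secondary granules, measured 194 ± 162 (SD, n = 3) in lung and 7104 ± 3983 (SD, n = 3) in spleen (-5.39, SE 0.93, adjusted p = 0.00321). Ngp, neutrophilic granule protein, was 283 ± 224 against 10100 ± 5679 (-5.35). Camp, the precursor of cathelicidin, was 32.1 ± 28.7 against 1063 ± 548 (-5.33). Chil3 (-3.36, adjusted p = 4.47e-05), Cd177 (-2.25, adjusted p = 9.57e-09) and the monocyte and neutrophil antigen gene Ly6c2 (-1.71) were lower in lung too. Of 13 granule genes, 10 were lower in lung (12 adjusted over the list alone) and 0 higher. Their median difference was -1.54 (adjusted p = 1.45e-17). The calls of Ltf, Ngp and Camp were lost without the 5 libraries under 250000 reads, with differences of -5.02, -5.12 and -5.25. The 13 measured cell cycle genes did not pass as a list. Top2a, which untangles DNA in dividing cells, was lower in lung (-2.54) but lost that call at equal depth (-1.11) and with any of 3 single libraries left out (-2.38 to -2.24). Stmn1, a regulator of microtubules, was higher (3.62).

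The inflammatory genes that set lung apart from blood also did so against spleen. Cxcl2 differed by 8.03 (adjusted p = 5.97e-14) and Ptgs2 by 7.89 (adjusted p = 9.42e-05) between GF lung and GF spleen, where they measured 1.69 ± 2.93 and 15.1 ± 15.02. NF-kB targets were higher in lung in 22 of 33 cases (24 adjusted over the list alone, median 2.29, adjusted p = 5.73e-24). Immediate early genes were higher in 16 of 28 (18 adjusted over the list alone) and lower in 1 (1 adjusted over the list alone, median 2.0, or 1.85 with genes at 0 reads at their bound, adjusted p = 1.73e-14). Angiogenesis genes were higher in 7 of 11 cases (7 adjusted over the list alone) and lower in 1 (1 adjusted over the list alone, 2.11, or 1.99 at the bound, adjusted p = 4.37e-05, and adjusted p = 0.0622 with an estimated correlation). Of 9 clock genes, Per1 (91.9 ± 5.33 against 16.02 ± 1.75) and Bhlhe40 were higher (4 adjusted over the list alone, 1.38, adjusted p = 0.00337). Both also respond to other stimuli. The lung cell markers moved with these groups, 22 of 25 higher (23 adjusted over the list alone, 4.30, or 4.28 at the bound, adjusted p = 5.43e-30). Sftpa1, a surfactant protein gene, was at 1106 ± 507 in lung and 0 reads in spleen (at least 283-fold higher). Higher as well were 12 of 13 mitochondrially encoded genes (13 adjusted over the list alone, 2.58, adjusted p = 2.24e-16). Macrophage markers passed as lower, with 3 of 16 lower and 2 higher (7 and 2 adjusted over the list alone, -0.77, adjusted p = 0.000528). The lower ones were Ly6c2, Chil3 and the haem-degrading enzyme gene Hmox1.

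Between GF lung and GF spleen 844 genes differed, 666 higher and 178 lower in lung. The share of higher genes was 78.9%, and 58.7% after quantile and 67.5% after median-ratio rescaling. These shifted the median difference of all genes from 0.11 to -0.12 and 0.00. Without lung GF replicate 4 the count was 560.

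**Figure D3:**
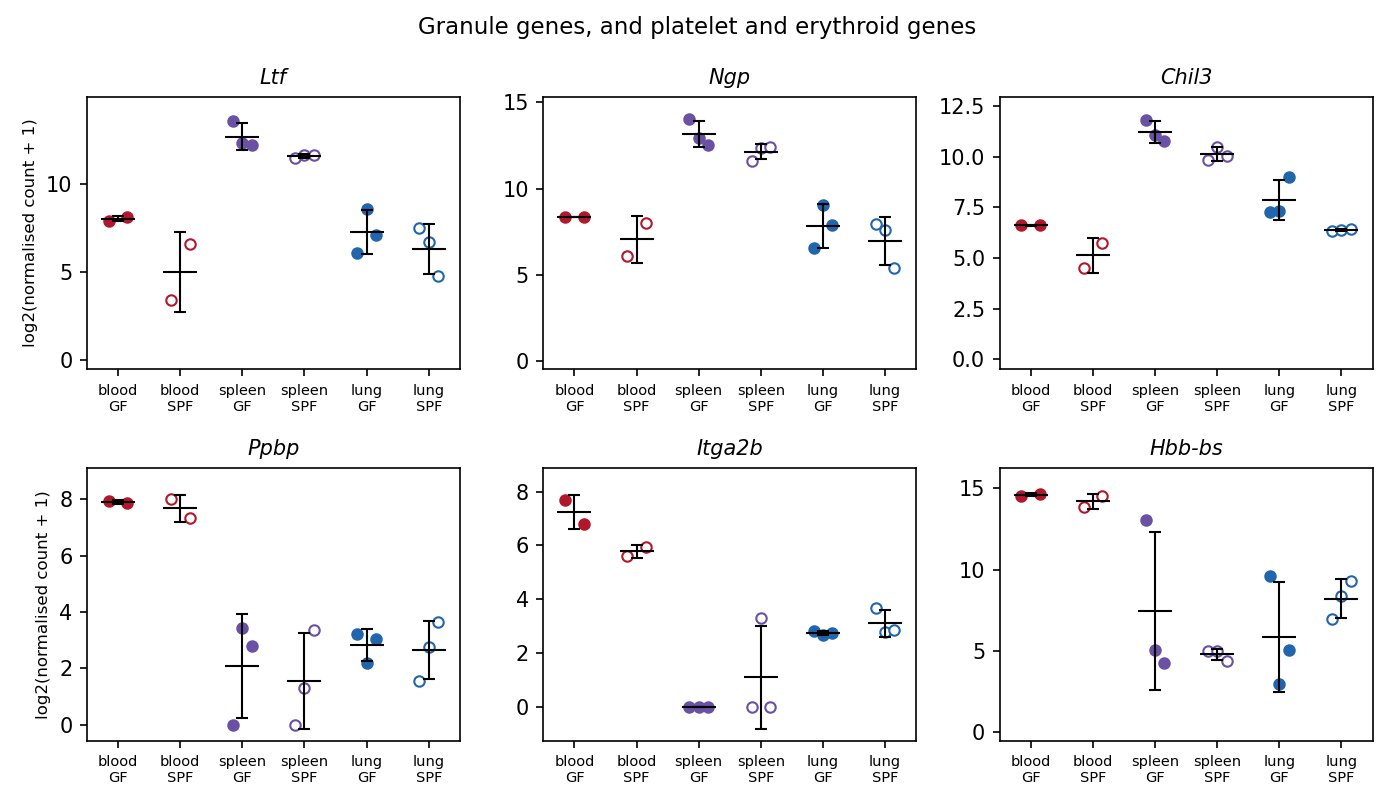
Each dot is the log2 of the normalised count plus 1 of a gene in 1 library (GF filled, SPF open) for the granule genes Ltf and Ngp, Chil3, the platelet genes Ppbp and Itga2b and the haemoglobin gene Hbb-bs, and bars give the mean and SD of a group (n = 2 in blood, n = 3 elsewhere). Ltf, Ngp and Chil3 are highest in the spleen libraries, and Ppbp, Itga2b and Hbb-bs in the blood libraries.

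The same tissue comparisons were made in SPF mice. Lung libraries of SPF mice again held more Cxcl2 (1398 ± 251, SD, n = 3) than blood libraries (1.07 ± 0.404, SD, n = 2), a difference of 9.26 (adjusted p = 7.61e-14). They also held more Egr1 (8.38) and more Thbs1, the matrix protein thrombospondin 1 (2168 ± 1169 against 22.1 ± 14.7; 6.57, adjusted p = 1.15e-06). NF-kB targets were higher in 23 of 33 cases (24 adjusted over the list alone) and lower in 1 (1 adjusted over the list alone, median 2.10, adjusted p = 9.79e-17). Immediate early genes were higher in 16 of 28 and lower in 1 (16 and 1 adjusted over the list alone, 1.5, adjusted p = 3.99e-08). Of 11 angiogenesis genes 7 were higher (8 adjusted over the list alone, 1.93, adjusted p = 1.1e-06). Lung cell markers moved with them, 22 of 25 higher and 2 lower (22 and 3 adjusted over the list alone, 4.32, or 5.15 at the bound, adjusted p = 9.79e-17). Sparc, a stromal matrix protein, was at 303 ± 109 in lung and 0 reads in SPF blood, at least 481-fold higher. So did 11 of 13 mitochondrially encoded genes (13 adjusted over the list alone, 2.18, adjusted p = 1.3e-10, and adjusted p = 0.0761 with an estimated correlation) and 7 of 12 MHC class II genes (10 adjusted over the list alone, 2.49, or 2.65 at the bound, adjusted p = 4.14e-06). B cell markers were higher in 9 of 13 cases and lower in 1 (9 and 2 adjusted over the list alone, 2.47, adjusted p = 0.0051, and adjusted p = 0.214 with an estimated correlation).

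Some interferon-stimulated genes, ribosomal protein genes and genes of oxidative phosphorylation were lower in SPF lung than in SPF blood, and these 3 lists lost their call with an estimated correlation. Oas1a, an antiviral nucleotide synthetase, measured 40.7 ± 22.9 in lung and 158 ± 6.34 in blood (-2.03, adjusted p = 0.000507). Irf7, a transcription factor of the interferon response, measured 284 ± 110.0 against 687 ± 11.97 (-1.34, adjusted p = 0.0015). Of 35 interferon response genes 14 were lower (17 adjusted over the list alone) and 0 higher (1 adjusted over the list alone, median -0.92, adjusted p = 4.64e-07, and adjusted p = 0.214 with an estimated correlation). The counts were 6 of 50 for oxidative phosphorylation (4 adjusted over the list alone, -0.62, adjusted p = 2.95e-05) and 4 of 55 for ribosomal proteins (2 adjusted over the list alone, -0.56, adjusted p = 7.43e-05). Each had adjusted p = 0.34 with an estimated correlation. The summed levels of these 3 lists were higher in SPF blood than in any other group. Interferon response genes summed to 10740 ± 615 there and to at most 7634 ± 527 elsewhere (GF spleen). The values were 5835 ± 603 and 3813 ± 1010 (GF blood) for oxidative phosphorylation, and 4110 ± 215 and 2601 ± 353 (SPF lung) for ribosomal proteins. Comparisons of SPF blood with SPF lung, SPF spleen and GF blood thus rest on the same 2 SPF blood libraries. In the hypoxia and glycolysis list 5 of 32 were higher and 9 lower (10 lower adjusted over the list alone), and the list did not pass (adjusted p = 0.0848). The glycolytic gene Gapdh was among the lower ones (1554 ± 29.4 against 4267 ± 224; -1.46, adjusted p = 7.56e-05). Platelet genes such as Ppbp were lower in lung (6.42 ± 4.77 against 209 ± 68.7). In their list 7 of 15 were lower and 1 higher (13 and 1 adjusted over the list alone, -4.32, adjusted p = 4.94e-09). In all 1585 genes differed, 1035 higher (65.3%) and 550 lower in lung. After quantile, median-ratio and TMM rescaling 57.3%, 52.9% and 55.4% were higher, and the median of all genes moved from 0.15 to -0.13, 0.00 and 0.03. The direction of the interferon, ribosomal and oxidative lists was the same under the 3 rescalings. The count was 704 without blood SPF replicate 3, 971 without blood SPF replicate 4 and 2628 without the 5 libraries under 250000 reads.

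Some granule transcripts were higher in spleen than in blood neutrophils of SPF mice, while the summed level of the list was 36130 ± 3360 in spleen and 30710 ± 5990 in blood. Ltf was 3034 ± 245 (SD, n = 3) in spleen and 53.2 ± 61.8 (SD, n = 2) in blood (6.55, SE 1.03, adjusted p = 0.00491). Chil3 was 1125 ± 278 against 36.9 ± 21.5 (4.99, adjusted p = 3.53e-05), and Cybb was higher by 1.73. Of 13 granule genes 5 were higher (6 adjusted over the list alone) and 0 lower (1 adjusted over the list alone, median 0.59, adjusted p = 4.27e-05, and adjusted p = 0.151 with an estimated correlation). The 13 cell cycle genes passed as a list with 1 higher and 1 lower (4 and 1 adjusted over the list alone, median 1.62, or 0.79 at the bound, adjusted p = 0.0346, and adjusted p = 0.313 with an estimated correlation). That list call was lost at equal depth, where the median was -0.39, and without blood SPF replicate 4 (1.40), spleen SPF replicate 2 (1.3) or spleen SPF replicate 4 (1.70). Isg15, an interferon-stimulated ubiquitin-like protein, was lower in spleen (34.6 ± 16.8 against 186 ± 11.99; -2.41, adjusted p = 9.98e-05). Of 35 interferon genes 7 were lower (12 adjusted over the list alone, -0.65, adjusted p = 2.61e-06). So were 6 of 50 oxidative phosphorylation genes (13 adjusted over the list alone, -0.85, adjusted p = 2.06e-08) and 7 of 55 ribosomal protein genes (7 adjusted over the list alone, -0.95, adjusted p = 8.45e-09). Each of these lists had adjusted p = 0.313 with an estimated correlation. Their summed levels were higher in SPF blood than in any other group. Macrophage markers were higher in 6 of 16 cases and lower in 1 (8 and 2 adjusted over the list alone, 0.65, adjusted p = 0.000369). MHC class II genes were higher in 4 of 12 (6 adjusted over the list alone, 1.45, adjusted p = 0.000156, and adjusted p = 0.151 with an estimated correlation). Of 15 erythroid and platelet genes 10 were lower (14 adjusted over the list alone, -3.44, adjusted p = 2.16e-15). The 586 genes that differed, 253 higher (43.2%, or 59.0% after quantile rescaling) and 333 lower, rested on the blood libraries. The count was 39 without blood SPF replicate 3 and 283 without blood SPF replicate 4. The call of Ltf was lost without blood SPF replicate 3 (4.95), without the 5 libraries under 250000 reads (6.62) and in a fit of the compared groups alone (6.55).

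In SPF mice as in GF mice, granule genes were lower and inflammatory genes higher in lung than in spleen. Chil3 was 81.6 ± 2.75 (SD, n = 3) in lung and 1125 ± 278 (SD, n = 3) in spleen (-3.73, adjusted p = 1.5e-05), and Cd177 was 189 ± 49.0 against 657 ± 55.2 (-1.82). Of 13 granule genes 8 were lower (10 adjusted over the list alone, median -1.25, adjusted p = 1.1e-13). Cxcl2 was at 0 reads in the SPF spleen libraries, so it was at least 473-fold higher in lung, and Trem1 was 5182 ± 986 against 460 ± 107 (3.49, adjusted p = 1.93e-14). NF-kB targets were higher in 24 of 33 cases (27 adjusted over the list alone, 2.73, adjusted p = 2.15e-32). Immediate early genes were higher in 18 of 28 and lower in 0 (21 and 1 adjusted over the list alone, 1.88, or 1.93 at the bound, adjusted p = 1.29e-17). Beside these stood 21 of 25 lung cell markers (22 adjusted over the list alone, 3.64, adjusted p = 1.27e-26) and 11 of 13 mitochondrially encoded genes (11 adjusted over the list alone, adjusted p = 1.36e-10, and adjusted p = 0.0938 with an estimated correlation). In all 802 genes differed, 637 higher (79.4%, or 60.6% after quantile rescaling, which moved the median of all genes from 0.06 to -0.12) and 165 lower.

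The GF and SPF versions of a tissue comparison share no library, but both use the spread of each gene estimated over all 16 libraries. Their calls may therefore overlap above the number for independent lists without a shared difference. In lung against spleen 434 genes passed as higher and 70 as lower in both, against 51.1 and 3.54 for independent lists of these sizes. For lung against blood the numbers were 511 and 113, against 81.1 and 10.8, and for spleen against blood 15 and 21, against 1.19 and 1.36.

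Microbial status was then compared within each tissue. In blood neutrophils the long noncoding RNA Malat1 (ENSMUSG00000092341, chromosome 19, 5795690 to 5802672) was lower in GF mice, 1527 ± 404 (SD, n = 2) against 7545 ± 1676 (SD, n = 2) in SPF mice (-2.31, SE 0.24, adjusted p = 1.97e-06). The MHC class I gene H2-K1 was 836 ± 50.1 against 3098 ± 157 (-1.89, adjusted p = 0.00102). Tlr13, a receptor for bacterial ribosomal RNA, was higher in GF mice, 975 ± 185 against 272 ± 52.1 (1.84, adjusted p = 0.000523). Thbs1 measured 184 ± 95.4 against 22.1 ± 14.7 (3.06, adjusted p = 0.0244). Oxidative phosphorylation and ribosomal protein genes lay lower in GF blood, each by a median of -0.85 (adjusted p = 7.63e-09 for both, and adjusted p = 0.518 for both with an estimated correlation). Singly 0 of 50 and 1 of 55 members passed (1 and 4 adjusted over the list alone). Interferon response genes had a median of -0.47 with 1 of 35 lower (3 adjusted over the list alone, adjusted p = 0.000276, and adjusted p = 0.518 with an estimated correlation). Mitochondrially encoded genes had one of -0.59 with 0 of 13 (2 adjusted over the list alone, adjusted p = 0.00884, and adjusted p = 0.532 with an estimated correlation). Erythroid and platelet markers had a median of 0.86 with 0 of 15 passing (0 adjusted over the list alone, adjusted p = 0.0369, and adjusted p = 0.518 with an estimated correlation). Granule genes had one of 0.65 with 0 of 13 (0 adjusted over the list alone, adjusted p = 0.0369, and adjusted p = 0.518 with an estimated correlation). The summed levels of the oxidative phosphorylation, ribosomal protein and interferon lists were higher in SPF blood than in any other group.

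Of the 8299 genes 110 passed in blood, 66 higher (60%, or 70.2% after quantile rescaling) and 44 lower in GF mice. With 2 libraries a group the count depended on each. It was 280 without blood GF replicate 2, 7 without blood GF replicate 3, 2 without blood SPF replicate 3 and 30 without blood SPF replicate 4. Leaving out libraries of other tissues, which share the estimate of spread, gave 203 (spleen GF replicate 1), 351 (spleen SPF replicate 1) and 72 (lung GF replicate 3). Without the trended and robust prior 0 genes passed in limma and 1254 had an unadjusted p under 0.05, while DESeq2 and edgeR on recovered reads called 433 and 391. The call of H2-K1 was lost without blood GF replicate 3 (-1.83) or blood SPF replicate 3 (-1.83), and that of Tlr13 without blood SPF replicate 3 (1.64). That of Thbs1 was lost without blood GF replicate 3 (2.50), blood SPF replicate 3 (3.75) or blood SPF replicate 4 (2.37). Malat1 passed with any 1 library left out.

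In spleen neutrophils Crispld2 (ENSMUSG00000031825, chromosome 8, 119992438 to 120052793), a secreted protein that binds lipopolysaccharide, was higher in GF mice, 393 ± 43.7 (SD, n = 3) against 99.1 ± 11.01 (SD, n = 3) in SPF mice (1.95, SE 0.32, adjusted p = 0.00305). Il1r2, the decoy receptor for interleukin 1, was 1805 ± 402 against 576 ± 186 (1.67, adjusted p = 0.00131). Hspa8, a constitutive chaperone, was 1510 ± 161 against 540 ± 97.9 (1.49, adjusted p = 0.00131). Lmnb1, a nuclear lamina protein, was 158 ± 23.3 against 52.1 ± 16.7 (1.57, adjusted p = 0.00305). The cold-inducible RNA-binding protein gene Rbm3 was lower, 35.7 ± 6.21 against 126 ± 51.4 (-1.68, adjusted p = 0.00514). Glucocorticoid response genes had a median of 0.80, with 1 of 14 passing (6 adjusted over the list alone, adjusted p = 3.41e-06, and adjusted p = 0.345 with an estimated correlation). Granule genes had a median of 0.61 (0 of 13, 2 adjusted over the list alone, adjusted p = 0.00199, and adjusted p = 0.384 with an estimated correlation). Interferon response genes had one of 0.35 (0 of 35, 2 adjusted over the list alone, adjusted p = 0.00218, and adjusted p = 0.63 with an estimated correlation). In all 27 genes passed, 21 higher and 6 lower in GF mice. The count was 220 without spleen SPF replicate 1, 10 without spleen GF replicate 4, 15 without spleen SPF replicate 2, 43 without spleen GF replicate 1 and 55 without spleen SPF replicate 4. Crispld2 passed with any 1 library left out but not without the 5 libraries under 250000 reads (1.61) or with voom weights (1.89). Without the trended and robust prior none of these 5 genes passed. Hspa8 was also lost without the 5 libraries under 250000 reads (1.39), and Lmnb1 and Rbm3 with voom weights (1.63 and -1.77).

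In lung neutrophils 2 genes passed. Crispld2 was higher in GF mice, 402 ± 71.8 (SD, n = 3) against 125 ± 85.7 (SD, n = 3; 1.87, SE 0.32, adjusted p = 0.0138). Ifngr2 (chromosome 16, 91547072 to 91565623), a subunit of the interferon gamma receptor, was lower, 49.9 ± 4.72 against 143 ± 11.5 (-1.49, SE 0.25, adjusted p = 0.0138). Ifngr2 also passed as lower in GF blood, 121 ± 24.9 against 299.6 ± 15.6 in SPF blood (SD, n = 2 each). In lung 332 genes had an unadjusted p under 0.05, and DESeq2, edgeR and voom gave 12, 7 and 4. The count was 0 without lung GF replicate 2, 3 or 4 and without lung SPF replicate 1 or 3, where Crispld2 differed by 1.49 to 2.0 and Ifngr2 by -1.56 to -1.43. It was 5 without lung SPF replicate 2. Lung cell markers lay higher in GF lung (median 0.68, 0 of 25 passing, 0 adjusted over the list alone, adjusted p = 8.88e-06, and adjusted p = 0.618 with an estimated correlation). So did mitochondrially encoded genes (0 of 13, adjusted p = 1.57e-07, and adjusted p = 0.422 with an estimated correlation). The summed level of the lung cell markers was 10950 ± 3880 against 5534 ± 1710. Glucocorticoid response genes (0 of 14, 1 adjusted over the list alone, adjusted p = 0.000552, and adjusted p = 0.422 with an estimated correlation) lay higher as well. Interferon response genes had a median of 0.30 there (0 of 35, 0 adjusted over the list alone, adjusted p = 0.000345, and adjusted p = 0.727 with an estimated correlation).

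**Figure D4:**
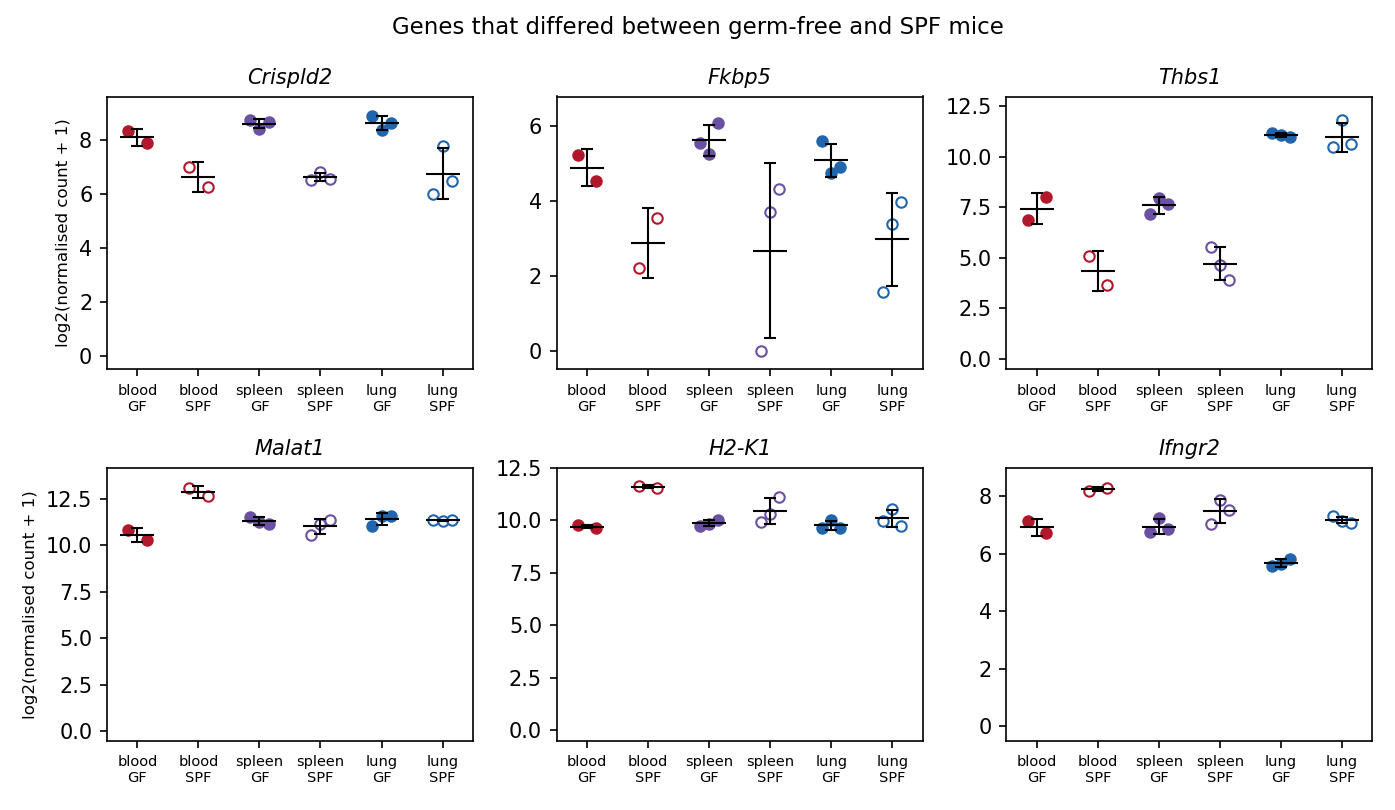
Each dot is the log2 of the normalised count plus 1 of a gene in 1 library (GF filled, SPF open) for Crispld2, Fkbp5, Thbs1, Malat1, H2-K1 and Ifngr2, and bars give the mean and SD of a group (n = 2 in blood, n = 3 elsewhere). Crispld2 lies higher in GF than in SPF libraries in each tissue, although blood did not pass (adjusted p = 0.0519), and Malat1 is lower in GF than in SPF blood.

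Averaged over the 3 tissues, with 8 GF and 8 SPF libraries, Crispld2 differed by 1.77 (SE 0.20, adjusted p = 1.92e-05) and Fkbp5, a chaperone of steroid receptors that glucocorticoids induce, by 2.07 (SE 0.35, adjusted p = 0.00184). Thbs1 (1.98, adjusted p = 0.00545), Tlr13 (1.01, adjusted p = 0.000205) and Hspa8 (0.78, adjusted p = 0.00314) were higher and Cirbp, a cold-inducible RNA-binding protein (-1.5, adjusted p = 0.0105), lower in GF mice. The average for Thbs1 came from blood (3.06) and spleen (2.78, adjusted p = 0.0255), while lung showed 2114 ± 145 (SD, n = 3) against 2168 ± 1169 (0.09, adjusted p = 0.999). Its spleen call was lost without spleen GF replicate 3 (2.60), spleen GF replicate 4 (2.75) or spleen SPF replicate 2 (2.71), and without the 5 libraries under 250000 reads (3.28), with voom weights (2.99) and with edgeR (3.003). The interactions of Thbs1 that set lung against blood and spleen were -2.97 and -2.69 and did not pass (adjusted p = 0.3 and 0.459). Of 14 glucocorticoid response genes 3 were higher, Fkbp5, Il1r2 and Pik3ip1 (3 adjusted over the list alone, median 0.47, adjusted p = 3.39e-05, and adjusted p = 0.236 with an estimated correlation). Of 13 granule genes 2 were higher, Cd177 and Chil3 (5 adjusted over the list alone, 0.35, adjusted p = 0.000192, and adjusted p = 0.236 with an estimated correlation). Among 32 pattern recognition genes Tlr2, Tlr4, Tlr7 and Tlr13 were higher (4 adjusted over the list alone) and 0 lower (1 adjusted over the list alone), and the list as a whole did not pass (adjusted p = 0.176). Lung cell markers had a median of 0.48 (adjusted p = 0.000595, and adjusted p = 0.518 with an estimated correlation). In all 115 genes passed, 78 higher and 37 lower. Of the list members, the calls were lost with any of 5 single libraries left out for Il1r2 (0.54 to 0.63) and Cd177 (0.56 to 0.66), of 9 for Pik3ip1 (1.07 to 1.36) and of 3 for Chil3 (1.17 to 1.37). They were lost with any of 10 for Tlr2 (0.53 to 0.69), of 13 for Tlr4 (0.59 to 0.73) and of 1 for Tlr7 (1.79, without blood GF replicate 3). The call of Fkbp5 was lost at equal depth (1.51), those of Crispld2 (1.72), Thbs1 (1.96) and Hspa8 (0.73) without the 5 libraries under 250000 reads, and that of Cirbp without blood GF replicate 3 (-1.44) or blood SPF replicate 4 (-1.40).

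The count of 115 moved with single libraries. It was 38 without blood GF replicate 3, 38 without blood SPF replicate 3, 39 without blood SPF replicate 4, 44 without lung SPF replicate 1 and 46 without lung GF replicate 2. It was 59 without lung GF replicate 4, 63 without lung SPF replicate 3, 66 without spleen GF replicate 4 and 73 without spleen SPF replicate 2. It was 177 without blood GF replicate 2, 223 without spleen GF replicate 1 and 368 without spleen SPF replicate 1. Without the 5 libraries under 250000 reads it was 186. No library is shared between the tissues, although the estimate of spread is, and the labels do not say whether animals are. In both blood and spleen 2 genes passed as higher in GF mice, against 0.17 for independent lists of these sizes, and 0 passed as lower in both. Of the blood calls, 38 of 66 higher and 22 of 44 lower genes had the same sign in spleen, and the differences in the 2 tissues correlated at 0.009 across genes, which are not independent replicates. In lung, 45 of the 66 and 37 of the 44 had the same sign as in blood, with a correlation of 0.238. Of the spleen calls, 17 of 21 higher and 3 of 6 lower genes had the same sign in lung, with a correlation of 0.053. Ifngr2 passed as lower in both blood and lung, and Crispld2 as higher in both spleen and lung.

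Whether a tissue difference depended on microbial status was tested as an interaction, the tissue difference in GF mice minus that in SPF mice. For spleen against blood 63 genes passed, 34 positive (54.0%, or 36.4% after quantile rescaling) and 29 negative. The interaction of Malat1 was 2.60 (adjusted p = 3.7e-05), and those of the interferon-induced genes Isg15 and Irf7 were 2.49 and 1.73 (adjusted p = 0.0191 and 0.0431). Of 35 interferon response genes these 2 passed (3 adjusted over the list alone, median 0.82, adjusted p = 6.15e-07, and adjusted p = 0.62 with an estimated correlation). Malat1 was higher in SPF blood (7545 ± 1676) than in any other group, the next highest being GF lung (2732 ± 578). The summed level of the interferon list was highest in SPF blood too. The count was 2 without blood GF replicate 3, 3 without blood SPF replicate 3, 5 without spleen SPF replicate 2, 13 without spleen GF replicate 3 and 24 without blood SPF replicate 4. It was 39, 40 and 40 without lung GF replicate 2, 3 and 4, which share the estimate of spread, and 110 without spleen SPF replicate 4, 169 without blood GF replicate 2 and 207 without spleen SPF replicate 1. The call of Isg15 was lost with any of 4 single libraries left out (2.42 to 2.83) and that of Irf7 with any of 10 (1.62 to 1.78). Malat1 passed with any 1 library left out.

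For lung against blood Malat1 alone passed (2.36, SE 0.32, adjusted p = 0.000253), with 623 genes at an unadjusted p under 0.05. For lung against spleen Lmnb1 alone passed (-2.17, SE 0.38, adjusted p = 0.0235), with 561. The call of Lmnb1 was lost with any of 6 single libraries left out (-2.12 to -2.04). The first count was 28 without blood GF replicate 2, 18 without spleen SPF replicate 1, 4 without spleen SPF replicate 4 and 2 without blood SPF replicate 4, lung SPF replicate 1 or lung SPF replicate 3. The second was 0 without spleen GF replicate 3 or 4, spleen SPF replicate 2, lung GF replicate 3 or lung SPF replicate 2 or 3. It was 48 without spleen SPF replicate 1, 4 without spleen GF replicate 1, spleen SPF replicate 4 or lung SPF replicate 1, 3 without either replicate of blood GF or blood SPF or lung GF replicate 2, and 2 without lung GF replicate 4. DESeq2 gave 91 genes for the first and 19 for the second, and edgeR 41 and 10.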

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

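Among the tests of this part, those of depth, other cell types and a glucocorticoid response, and the results with voom weights and without the shallow libraries, were chosen only after the result was seen; the counts over other splits of the samples were planned.

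The 3 interactions are listed here because some genes passed a direct test of whether the effect of microbial status differed between tissues. The numbers of genes were 63 for spleen against blood, 1 for lung against blood (Malat1) and 1 for lung against spleen (Lmnb1). The first count was 5 without spleen SPF replicate 2 and 207 without spleen SPF replicate 1. Without the trended and robust prior no gene passed in any of the 3. Of 100 splits of the libraries within tissues, the real one among them, 16 gave at least 1 gene for lung against spleen. The highest other split gave 82, so chance was not excluded. A split calling that many genes may reflect a structure of the samples other than status, unequal depth included, which was not tested. Interactions with blood were not set against other splits. Malat1 was lower in GF than in SPF blood, while Lmnb1 was higher in GF than in SPF spleen. A biological difference between tissues in the response to the microbiota stays open and was not tested apart from these models.

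Crispld2 and the glucocorticoid response gene Fkbp5 were higher in GF mice when averaged over tissues. All 6 differences, 2 genes in 3 tissues, were positive and the smallest was 1.49 on the log2 scale, but only Crispld2 in spleen and lung passed (adjusted p = 0.0519 for Crispld2 in blood, and 0.122, 0.0785 and 0.999 for Fkbp5 in blood, spleen and lung). Both genes were picked by their average over the same tissues, which favours a difference in each. The 6 differences are therefore only weak evidence against RNA of other cell types of 1 tissue as the whole cause for Crispld2. They are weaker evidence for Fkbp5, whose lung difference at equal depth was 1.11 (SE 0.76). At equal depth the smaller of the averaged differences was 1.51, that of Fkbp5, so depth as the whole cause is argued against as well, although the call of Fkbp5 ended because its SE rose from 0.35 to 0.47 and the difference fell from 2.07, while Crispld2 stayed past the threshold (1.77, then 2.13). A glucocorticoid response may be present but cannot be told apart from a change in these genes alone (14 genes measured, adjusted p = 0.236 with an estimated correlation). Of 100 splits within tissues 5, the real one among them, gave some gene a limma p as small as that of Crispld2 (2.31e-09, smallest other 3.08e-10). Chance was thus not excluded, and an effect of the microbiota remains an open hypothesis.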

How the results depend on the processing

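The tests with voom weights, with libraries thinned to equal depth and without the 5 libraries under 250000 reads were chosen only after the depths were seen. Depth limited genes with few reads. One read was worth up to 7.62 normalised counts, genes at 0 reads stood higher in shallow libraries, and 37.7% of genes had 0 reads in the library most affected. Over 32 settings, the named genes kept direction and threshold in 14208 values, lost the threshold in 1663 and reversed in 2. The 100 passing list results were run under 25 of these settings, not with other weights, other tools, another prior, the block or the compared groups alone, and the numbers were 2284, 205 and 8.

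Counts of genes moved by over 1.5 times as follows, and the cause was not tested except where fewer genes or libraries were used. With a limit of 100, which left fewer genes, lung minus blood gave 384 in GF and 921 in SPF mice, spleen minus blood in GF 44, lung minus spleen 365 in GF and 419 in SPF mice. GF minus SPF gave 250 in blood and 196 averaged, the interaction of lung and spleen 4, and 63 lists passed. At equal depth lung minus blood gave 382 in GF and 636 in SPF mice, spleen minus blood 39 and 253, and lung minus spleen 454 and 429. GF minus SPF then gave 17 in spleen, 0 in lung (limma, 496 at an unadjusted p under 0.05) and 51 averaged, and the interactions of lung and blood, spleen and blood, and lung and spleen gave 6, 26 and 4.

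Voom weights gave 1454 for lung minus blood in GF and 3109 in SPF mice, and 1075 for spleen minus blood in SPF. GF minus SPF gave 780 in blood, 4 in spleen, 4 in lung and 212 averaged, and the interactions 67, 139 and 0 (568 at an unadjusted p under 0.05). With edgeR lung minus blood gave 1243 in GF and 2546 in SPF mice and spleen minus blood in SPF 950. GF minus SPF gave 391 in blood, 7 in lung and 254 averaged, and the interactions 41, 140 and 10. DESeq2 gave 433, 64, 12 and 270 for GF minus SPF in blood, spleen, lung and averaged, and 91, 193 and 19 for the interactions. Array weights gave 2707 for lung minus blood and 1022 for spleen minus blood in SPF, 288, 49, 1 and 276 for GF minus SPF in blood, spleen, lung and averaged, and 37, 101 and 23 for the interactions.

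Without the 5 libraries under 250000 reads spleen minus blood gave 114 in GF and 368 in SPF mice and lung minus blood in SPF 2628. GF minus SPF gave 169 in blood, 60 in spleen, 1 in lung and 186 averaged, and the interactions of lung with blood and with spleen 18 and 34. In fits of the compared groups alone lung minus blood in SPF gave 2489 and spleen minus blood in SPF 161, GF minus SPF 611 in blood and 14 in lung, and the interactions 51, 7 and 4. Without the trended and robust prior spleen minus blood in SPF gave 129 and GF minus SPF 14 in spleen and 10 averaged. It gave 0 in blood and 0 in lung (limma, 1254 and 338 at an unadjusted p under 0.05) and 0 for each of the 3 interactions (526, 1046 and 584). Quantile normalization gave 329 for spleen minus blood in SPF, and 3 for each interaction of lung. No filter gave 3 and 4 for these 2 interactions, and a pseudocount of 5, median-ratio and TMM rescaling each gave 4 for that of lung and spleen. With an estimated correlation 30 lists passed.

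Cxcr2 (0.054) and C5ar1 (0.11) reversed in SPF spleen minus blood under quantile normalization, as did the ageing receptors (0.082). With the limit of 100 the B cell list reversed in GF lung minus blood (-0.32), GF spleen minus blood (-0.057), SPF lung minus blood (-0.74) and SPF spleen minus blood (-0.29). So did the eosinophil list in GF lung minus blood (-0.10) and the cell cycle list in SPF spleen minus blood (-1.01), the latter also at equal depth (-0.39). The limit left fewer genes in these lists.

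With 1 library left out at a time, the counts ran from 524 to 1023 for lung minus blood, 29 to 153 for spleen minus blood and 560 to 1020 for lung minus spleen in GF mice. In SPF mice they ran from 704 to 1864, 39 to 730 and 540 to 987. GF minus SPF gave 2 to 351 in blood, 10 to 220 in spleen, 0 to 5 in lung (186 to 309 at an unadjusted p under 0.05 where it was 0) and 38 to 368 averaged. The interactions gave 1 to 28 for lung and blood, 2 to 207 for spleen and blood and 0 to 48 for lung and spleen (465 to 623 where it was 0). Lists passing numbered 91 to 105.

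No pairing of libraries by shared replicate number was seen, and the labels do not say whether a number marks an animal. Deviations from group means of 9 pairs of libraries with the same status and number correlated at a median of -0.02 (-0.13 to 0.07), and 0 pairs exceeded 0.1. The check cannot exclude pairing, since the means came from 2 or 3 libraries and the 2 deviations of a blood group mirror each other. For genes, the replicate block allowed for a correlation between libraries of the same status and number in tissue comparisons and interactions. For GF minus SPF it took the replicate number alone as a further term in the model. It moved the count for GF minus SPF in spleen to 51 and no other count by over 1.5 times. Sharing of animals between tissues was thus not modelled for GF minus SPF, including the average.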

Other observations

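In this part the tests of the patterns, including those at equal depth, were chosen only after the result was seen, while the counts over other splits were planned. Clock genes were higher in SPF lung than in SPF blood in 4 of 9 cases, Per1, Nr1d1, Tef and Bhlhe40 (5 adjusted over the list alone; median 1.64, adjusted p = 0.00357; adjusted p = 0.0395 with an estimated correlation). The call of Tef was lost without blood SPF replicate 3 (1.80) or lung SPF replicate 3 (1.89), after quantile rescaling (1.06) and at equal depth (0.43), where Per1 (1.94) and Nr1d1 (0.91) lost theirs too. The oxidase and phagocytosis list went both ways between SPF lung and SPF blood and did not pass, with 4 of 19 higher and 6 lower in lung (4 and 6 adjusted over the list alone; median -0.48, mean 0.22, adjusted p = 0.114). Rac2 (-1.48) and Fcer1g (-1.45) were among the lower and Cd36 (6.33) and Itgam (1.12) among the higher genes. The lysosome list did not pass either, with 5 of 32 higher and 7 lower (8 and 8 adjusted over the list alone; median -0.22, mean 0.28, adjusted p = 0.258), where Ctsl (2.02) was higher and Ctsd (-1.15, lost after quantile rescaling, -0.47) lower in SPF lung than in SPF blood. Between SPF lung and spleen, Il1r2 measured 3609 ± 643 (SD, n = 3) against 576 ± 186, Slc16a3, a lactate transporter, 2349 ± 478 against 253 ± 32.1, and Cxcr4 234 ± 43.1 against 70.0 ± 26.5. Across the 6 lung libraries the slope of mitochondrially encoded genes on the lung structural list was 0.848 (0.392 to 1.602 with 1 library left out), a relation that did not pass (exact permutation, r = 0.769, p = 0.0833, adjusted 0.25; rho = 0.943, p = 0.0167; r = 0.841 without the 2 libraries farthest from the median). Both lists lay higher in GF than in SPF lung, so status was not separated from it. Ageing receptors were lower in SPF spleen than in SPF blood by a median of -0.43, with 2 of 20 higher and 5 lower (2 and 7 adjusted over the list alone; adjusted p = 0.0192; adjusted p = 0.313 with an estimated correlation), but the median was 0.08 after quantile rescaling.

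The real groupings were set against other splits of the same libraries. For lung against spleen there were 844 genes in GF mice (highest other split 0) and 802 in SPF mice (highest other 3), for GF minus SPF in lung 2 (highest other 0) and for GF minus SPF in spleen 27 (highest other 256). Each of these comparisons has 10 splits, too few for a share under 0.05. The split of the spleen libraries that gave 256 may reflect a structure of the samples apart from status, unequal depth included, which was not tested. For the averaged contrast 5 of 100 splits within tissues, the real one among the 5, gave at least 115 genes. The highest other gave 522, so chance was not excluded, and that split too may reflect a structure of the samples.

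NF-kB targets and immediate early genes were higher in lung than in spleen and blood. RNA of lung epithelial, endothelial and stromal cells, which the Ly6G sort should remove, was a candidate source (Sftpc at 5533 in GF lung). It would raise both lists with the lung structural list across the 6 lung libraries. The highest slope with 1 library left out was 0.318. The list means include members that did not differ between tissues, which lowers the slope under this source too. RNA of these cells was therefore not excluded as a source. Of 3 such relations, the third being that of the mitochondrial genes above, exact permutation gave r = 0.165 (p = 0.749, adjusted 0.749) and rho = 0.086 (p = 0.919) for NF-kB targets, and r = 0.459 (p = 0.367, adjusted 0.55) and rho = 0.486 (p = 0.356) for immediate early genes, with r = 0.257 and 0.191 without the 2 libraries farthest from the median. Status was not separated from these relations. The structural list summed to 10950 ± 3880 in GF and 5534 ± 1710 in SPF lung, and NF-kB targets to 51380 ± 6660 and 58580 ± 4560. At equal depth 17 NF-kB targets passed as higher in lung than in spleen of GF mice, which argues against depth as the whole cause for them there. Immediate early genes and the contrast with blood were not counted in this way. Tissue preparation before sorting, which may induce such genes, cannot be told apart from a state of lung neutrophils, since preparation went with tissue, and 1 immediate early gene, Nr4a1, passed as higher in GF spleen than in GF blood.

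Granule genes were higher in spleen than in lung. At equal depth 8 granule genes passed in GF mice, which argues against depth as the whole cause. A candidate source is dividing neutrophil precursors in spleen. The cell cycle list passed as higher in SPF spleen than in SPF blood (1.62, or 0.79 with genes at 0 reads at their bound; adjusted p = 0.313 with an estimated correlation; -0.39 at equal depth), but at most 1 cell cycle gene passed singly as higher in spleen in any of 4 tissue comparisons, and the 13 measured cell cycle genes had a median of 1 read in spleen libraries. At that depth precursors cannot be told apart from mature neutrophils with more granule transcripts, and a difference between the tissues stays open.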
